A study of Mus musculus with 12 samples.

How the data were processed

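Gene expression was measured in mouse striatum, the nucleus accumbens included, on 12 Affymetrix mouse expression arrays. Per the labels' protocols, the animals were female littermates aged 10 to 15 weeks. They were caged singly, handled for 5 days, injected intraperitoneally and killed 1 hour later. The treatment text of every sample, those titled saline included, gives the injection as 25 mg/kg cocaine; that some animals received saline is taken from the titles and the series design. Per the labels' protocols, brains were kept in an RNA preservative, cut into sections of 150 µm, the striatum was dissected out with needles, and 2 µg of total RNA per sample was biotin-labelled. Each array holds 1 sample, which the titles call a biological replicate.

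The deposited values are log2 signals, 1 per probe set and array, made by the authors with GCRMA (background correction by probe sequence, normalisation between arrays and 1 value per probe set) in R 2.4.1, per the submitters' processing notes. The log base and the GCRMA options are not given in the sources used here. The lowest value of an array lay between 1.26 and 1.29 and the highest between 13.0 and 13.1, the usual range of GCRMA output in log2, so differences are given as log2 and folds as powers of 2. Array medians lay between 3.75 and 3.78, so the arrays had been brought to a common level before deposit and a shift common to all genes of an array would no longer be visible. GCRMA compresses the values of dim probe sets near background, so folds measured from levels near or under a log2 signal of 4 depend on its background correction. The number of arrays limits the precision.

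Groups were taken from the sample titles, which name the genotype (mutant or control), the treatment and a replicate number, with 3 arrays in each of 4 groups. The description field gives other groups (3 arrays as control saline, 5 as control cocaine and 4 as mutant cocaine). Arrays described there as mutant had Srf signals of 6.97 to 7.21, and arrays described as saline-treated controls 5.33 to 5.49, opposite to what a mutation that lowers Srf gives. The titles were therefore kept, as had been fixed before the data were examined. The series title names the serum response factor SRF; the labels used here do not say which part of Srf was changed or in which cells.

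The table held 22690 probe sets. After 64 control probe sets were left out, a probe set was tested if its log2 signal exceeded 4 in at least 3 of the 12 arrays, whatever their group, which left 11102. Of all probe sets, 20393 carried 1 gene symbol, 691 several and 1606 none in the platform annotation; probe sets with several symbols or none were tested and counted but not named. The Entrez identifiers of 20364 probe sets were found in a RefSeq gene table of assembly GRCm38.p6, 0 symbols needed updating, and 29 kept the name of the annotation. This table served only for names and for which genes are neighbours, since the files name no genome build. The tested probe sets stood for 6651 genes.

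All tests used limma 3.58.1 in R 4.3.3 on the deposited log2 signals, with a mean for each of the 4 groups, all 12 arrays in 1 fit, empirical Bayes moderation (8 residual and 4.71 prior degrees of freedom) and Benjamini-Hochberg adjustment over the probe sets tested. A probe set was called at a two-sided adjusted p under 0.05. The contrasts were cocaine against saline in each genotype and averaged over both, mutant against control in each treatment and averaged over both, and the difference between the genotypes' responses (the interaction). Every adjusted p printed for a gene is limma's, and errors of fold changes are limma's standard errors (SE).

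For gene lists, 1 probe set per gene was kept (the highest mean signal among those with exactly 1 symbol), and 26 lists fixed before the data were examined were tested with camera at a preset inter-gene correlation of 0.01, adjusted over lists within a contrast, and again with the correlation estimated for each list. Members called were counted over all probe sets tested and adjusted over the list alone. The genes called for cocaine averaged over both genotypes were used to compare the mean response of the genotypes, with an exact permutation test over all 400 relabellings of genotype within treatment, two-sided, whose smallest possible p is 0.005. In this balanced design the averaged effect is orthogonal to the difference between genotypes, so the choice of genes favours neither.

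Named genes follow a rule fixed before the data were examined. For each contrast these were Srf, up to 10 rising and 10 falling genes with the largest called changes whose groups did not overlap (in averaged contrasts, with the same sign in both parts), up to 4 called members of each list with any, and that list's brightest uncalled member. For the difference in response, the 10 largest responders to cocaine were added. Other list members and genes are named where a count is spelled out and were then chosen after their values were seen.

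The fit was tested on simulated data, 20 simulations of 11102 probe sets in which sets of probe sets were shifted. For cocaine in controls, shifts of 0.5, 1 and 2 log2 units were recovered in 68.2%, 99.1% and 99.9% of cases. For the difference in response the recovery was 22.6%, 92.5% and 99.6%. In the list test, a list of 15 genes shifted by 0.5 was called in 20 of 20 simulations under both settings, and 2 of 400 unchanged lists were called at the preset correlation and 0 of 400 with the estimated one. The simulated probe sets varied independently of each other. These rates therefore do not cover lists whose genes vary together, such as the immediate early transcription factors (estimated correlation 0.288).

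Alternatives covered the filter, the variance prior, array weights, further median or quantile scaling, the samples in the fit, the replicate number as a block, 1 probe set or the mean of the probe sets per gene, the median over responding genes, a looser threshold of 0.1, the inter-gene correlation, the description field as source of the groups, and each array left out in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.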

Results

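Transcript levels were compared in the striatum of control and SRF mutant mice 1 hour after an injection of saline or of 25 mg/kg cocaine, a psychostimulant that blocks dopamine reuptake. There were 3 arrays in each of the 4 groups. SRF is a transcription factor that binds serum response elements in immediate early genes and in genes of the actin cytoskeleton. The series title gives the question as the part SRF plays in transcription driven by activity. Correlations of the arrays over tested probe sets were 0.986 to 0.993 within groups and 0.976 to 0.990 between groups. The spread is that between the samples the titles call biological replicates.

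Srf itself was low in every mutant array. The tested probe set read 7.11, 7.21 and 7.18 in the saline-treated controls and 7.13, 7.20 and 6.97 in the cocaine-treated controls. In mutants it read 5.28, 5.27 and 5.01 after saline and 5.33, 5.46 and 5.49 after cocaine. The group means were 7.16 ± 0.0493, 7.10 ± 0.118, 5.19 ± 0.152 and 5.43 ± 0.0841 (log2, SD, n = 3 each), and Srf was 3.54-fold lower in mutants over both treatments (log2 change −1.83, SE 0.0662, adjusted p = 5.7e-09). A second Srf probe set lay below the filter in all groups, with means of 2.73 to 3.24. Cocaine left Srf without a called change in controls (−0.06, adjusted p = 0.979) and in mutants (0.24, adjusted p = 0.342).

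**Figure D1:**
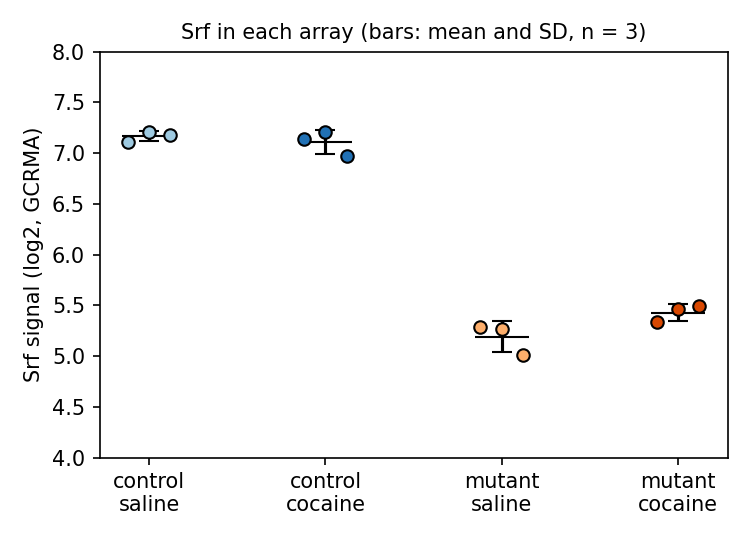
Srf signal (log2, y axis) in each of the 12 arrays by group (x axis), with the mean and SD of 3 arrays as bars. All 6 mutant arrays lie between 5.01 and 5.49 and all 6 control arrays between 6.97 and 7.21.

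In control animals, cocaine raised immediate early genes, the genes that neurons switch on within minutes of activation. Fos, a component of the AP-1 transcription factor, rose 17.9-fold (log2 change 4.16, SE 0.394, adjusted p = 1e-04). Egr2, a zinc finger transcription factor, rose 14.7-fold (3.88, SE 0.108, adjusted p = 4.17e-10), and Arc, which encodes a postsynaptic protein that regulates AMPA receptor traffic, rose 12-fold (3.59, SE 0.284, adjusted p = 1.59e-05). The orphan nuclear receptor Nr4a1 rose 7.42-fold, Egr4 7.09-fold, Junb 6.92-fold, Tiparp 6.19-fold and the MAP kinase phosphatase Dusp1 4.88-fold. Fosb rose 4.51-fold and Btg2 4.01-fold. The saline levels of Egr4 (1.90), Fosb (2.22) and Btg2 (3.65) in controls lay under the filter's floor of 4, where folds depend on the background correction.

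Over all tested probe sets, 50 were called in controls, 50 higher and 0 lower, standing for 39 genes. At an unadjusted p under 0.05, 704 probe sets passed, 461 of them higher. Of 14 tested immediate early transcription factors, 9 rose and 0 fell (12 rose adjusted over the list alone), with a median change of 1.73; Jund, the brightest member not called, read 0.19. Activity-regulated effector genes gave 7 risers of 16 (10 adjusted over the list alone), among them Arc, Tiparp, Gadd45b (log2 change 1.86) and Sertad1 (1.61). The list of immediate early genes known to be bound by SRF had 9 risers of 10 members, also 9 adjusted over the list alone, and its remaining member was Srf. CREB-bound genes had 3 risers of 9 (4 adjusted over the list alone), Dusp1, Gadd45b and the clock gene Per1 (1.23). MAPK feedback regulators had 2 of 9 (4 adjusted over the list alone), Dusp1 and Dusp6 (1.61), while Dusp14 read 1.12 at an adjusted p of 0.126.

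These 5 lists were called by camera in controls, and all 5 calls held with an estimated correlation (adjusted p = 0.00128 for the transcription factors, 0.00171 for effectors, 0.000908 for SRF-bound, 0.00552 for CREB-bound and 0.0352 for MAPK feedback genes). A sixth list, glucocorticoid-responsive genes, was called with only Per1 rising of 13 (1 adjusted over the list alone), and that call was lost (adjusted p = 0.154 with an estimated correlation). The astrocyte, oligodendrocyte, microglia and endothelial lists had 0 members called by limma in controls, and none of these lists was called by camera. With array weights in the fit, 88 probe sets were called for cocaine in controls.

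In mutants, cocaine again raised immediate early genes. Fos rose 12.5-fold (log2 change 3.64, SE 0.394, adjusted p = 0.000191), Tiparp 7.87-fold, Fosb 7.72-fold, Junb 7.68-fold and Arc 6.51-fold (2.70, SE 0.284, adjusted p = 0.000163). Dusp1 rose 5.70-fold, Nr4a1 4.85-fold and Gadd45b 4.47-fold. The saline level of Fosb in mutants (2.76) lay under the filter's floor of 4. Sstr2, a somatostatin receptor, rose 5.77-fold and the imprinted gene Mest 4.35-fold. Egr2 (−0.06, SE 0.108, adjusted p = 0.925; its other probe set 0.29, also not called) and Egr4 (0.01, SE 0.161, adjusted p = 0.997) did not pass the test.

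In all, 213 probe sets were called in mutants, 195 higher and 18 lower, standing for 132 and 10 genes, and 1193 passed an unadjusted p under 0.05. Without replicate 1 of the cocaine-treated mutants the number was 131, and without their replicate 2 it was 141. Of the 50 probe sets called in controls, 40 were also called as higher in mutants, where 0.878 would be shared by independent lists. The comparisons have no arrays in common. The falling genes had changes of up to −1.02, seen for the astrocyte filament gene Gfap (SE 0.217, adjusted p = 0.0303), which was the called member among 15 astrocyte genes. Others that fell were Myo7a (−0.67), the ribosomal protein gene Rpl27a (−0.66) and Cabp1 (−0.56), which encodes a neuronal calcium-binding protein. Gfap read 5.05 ± 0.461 and 4.03 ± 0.392 in mutants after saline and cocaine, against 4.26 ± 0.0388 and 4.06 ± 0.211 in controls (log2, SD, n = 3 each). In mutants Myo7a went from 4.03 to 3.35 and Cabp1 from 4.315 to 3.75. The levels of Gfap, Myo7a and Cabp1 in cocaine-treated mutants lay near or under the filter's floor of 4, where folds depend on the background correction.

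Among the lists, 8 of 14 immediate early transcription factors rose in mutants (9 adjusted over the list alone), 8 of 16 effector genes (13 adjusted over the list alone), 6 of 10 SRF-bound immediate early genes (8 adjusted over the list alone) and 4 of 9 CREB-bound genes (5 adjusted over the list alone), the last including Crem (1.13). These 4 calls held with an estimated correlation (adjusted p = 0.0168, 0.00449, 0.0142 and 0.0142), as did that of glucocorticoid-responsive genes (adjusted p = 0.0151), where Per1 and Errfi1 rose of 13 members (10 adjusted over the list alone). MAPK feedback regulators had 3 risers of 9 (5 adjusted over the list alone), a call lost at adjusted p = 0.0885 with an estimated correlation. Heat shock and unfolded protein genes had 3 risers of 12, the chaperone Dnajb1 (1.26) and the stress-induced transcription factors Atf4 (0.64, 1 of its 2 probe sets called) and Ddit3 (0.44). Adjusted over the list alone 5 rose and 1 fell, and the call was lost at adjusted p = 0.109 with an estimated correlation. Clock genes had 2 risers of 14, Per1 and Bhlhe40 (3 adjusted over the list alone; adjusted p = 0.109 with an estimated correlation). Glial activation had 3 tested members, of which Gfap fell (2 fell adjusted over the list alone; adjusted p = 0.0823 with an estimated correlation).

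Egr2 and Egr4 were the genes whose response to cocaine was smaller in mutants by the test of the difference itself. Egr2 read 4.0 ± 0.126 and 7.87 ± 0.174 in controls after saline and cocaine, against 3.83 ± 0.0587 and 3.77 ± 0.158 in mutants (log2, SD, n = 3 each). Its response differed by −3.94 (SE 0.153, adjusted p = 2.63e-08), and both of its probe sets were called. Egr4 went from 1.90 ± 0.202 to 4.73 ± 0.411 in controls and from 2.11 ± 0.0382 to 2.12 ± 0.00444 in mutants (log2, SD, n = 3 each), a difference of −2.82 (SE 0.228, adjusted p = 7e-05); the levels outside cocaine-treated controls lay below the filter's floor of 4. The Egr2 levels outside cocaine-treated controls were also at or near that floor.

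A further 5 genes responded more in mutants. Sstr2 read 0.68 in controls, short of the threshold, and rose by 2.53 in mutants (difference 1.85, SE 0.204, adjusted p = 0.00146). Taf1a, a subunit of an RNA polymerase I initiation factor, read 0.06 in controls and rose by 1.62 in mutants (difference 1.56, SE 0.172, adjusted p = 0.00146). The telomere protein gene Tinf2 differed by 1.25 (SE 0.163, adjusted p = 0.00726), the orphan receptor gene Gpr19 by 1.12 (SE 0.178, adjusted p = 0.0436) and the zinc finger gene Zfp948 by 0.98 (SE 0.148, adjusted p = 0.0309). The calls of Gpr19 and Zfp948 were lost in 10 and 9 of the 12 fits that left out 1 array, with adjusted p up to 0.188 and 0.138. Without the filter on dim probe sets, 5 probe sets were called in place of 8, and Tinf2, Gpr19 and Zfp948 were not called (adjusted p = 0.0921, 0.233 and 0.137).

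**Figure D2:**
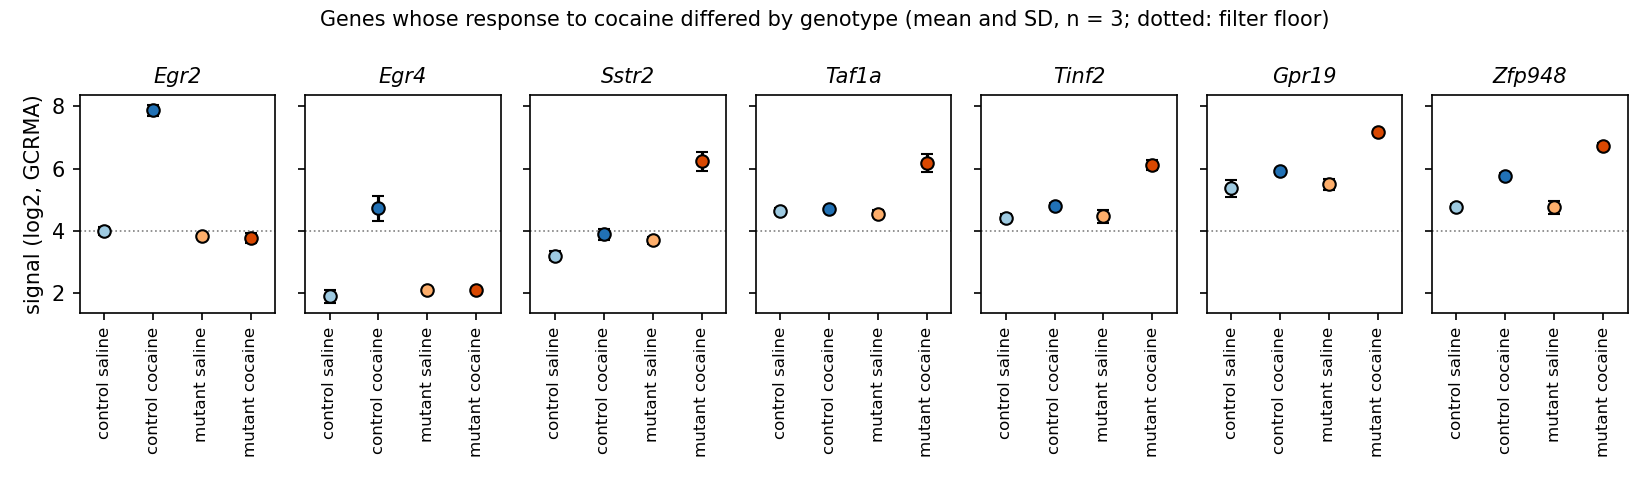
Signal (log2, y axis) of the 7 genes whose response to cocaine differed by genotype, by group (x axis), as mean and SD of 3 arrays; the dotted line is the filter's floor of 4. Egr2 stands at 7.87 and Egr4 at 4.73 in cocaine-treated controls alone, and Sstr2, Taf1a, Tinf2, Gpr19 and Zfp948 are highest in cocaine-treated mutants.

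The difference in response was called for 8 probe sets, 5 larger and 3 smaller in mutants, and 553 passed an unadjusted p under 0.05, where chance alone would give 555. Of the 10 largest responders over both genotypes, Egr2 was called for a difference and the others were not. Fos differed by −0.52 (SE 0.557), Arc by −0.89 (SE 0.401), Nr4a1 by −0.61 (SE 0.194, adjusted p = 0.722), Fosb by 0.77 (SE 0.367) and Junb by 0.15 (SE 0.308). Tiparp differed by 0.35 (SE 0.198), Gadd45b by 0.30 (SE 0.271), Dusp1 by 0.23 (SE 0.371) and Frmd6 by 0.22 (SE 0.147). Egr1, the brightest uncalled member of the immediate early transcription factors, rose by 1.34 in controls and by 0.64 in mutants. Its difference of −0.71 (SE 0.158) had an adjusted p of 0.32 over all probe sets.

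Among the SRF-bound immediate early genes, 2 of 10 had a smaller response in mutants, and 4 adjusted over the list alone (Egr2, Egr4, Egr1 and Nr4a1), with a median difference of −0.57. Of the immediate early transcription factors 2 of 14 had a smaller response, and the same 4 genes adjusted over the list alone. Both lists were called at the preset correlation and neither with the estimated one (adjusted p = 0.309 with an estimated correlation for each).

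The 154 genes called as higher with cocaine over both genotypes had a mean response of 0.64 in controls and 0.87 in mutants. The difference of 0.23 (SE 0.0745) did not pass the exact permutation test (p = 0.215 over 400 relabellings). Relabelling within a treatment also brings the genotypes' differences in level into the term tested. The response was larger in mutants for 121 of the 154 genes (78.6%). The 14 genes called as lower responded by −0.28 in controls and −0.40 in mutants, a difference of −0.12 (SE 0.0236, exact permutation p = 0.09). It passed the threshold without the filter (exact permutation p = 0.015) and without replicate 3 of the saline-treated mutants (exact permutation p = 0.02), and its sign turned, to 0.010, without replicate 1 of the saline-treated controls. It was smaller with the stricter filter (−0.036, exact permutation p = 0.36) and as a median over the genes (−0.059, exact permutation p = 0.72).

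**Figure D3:**
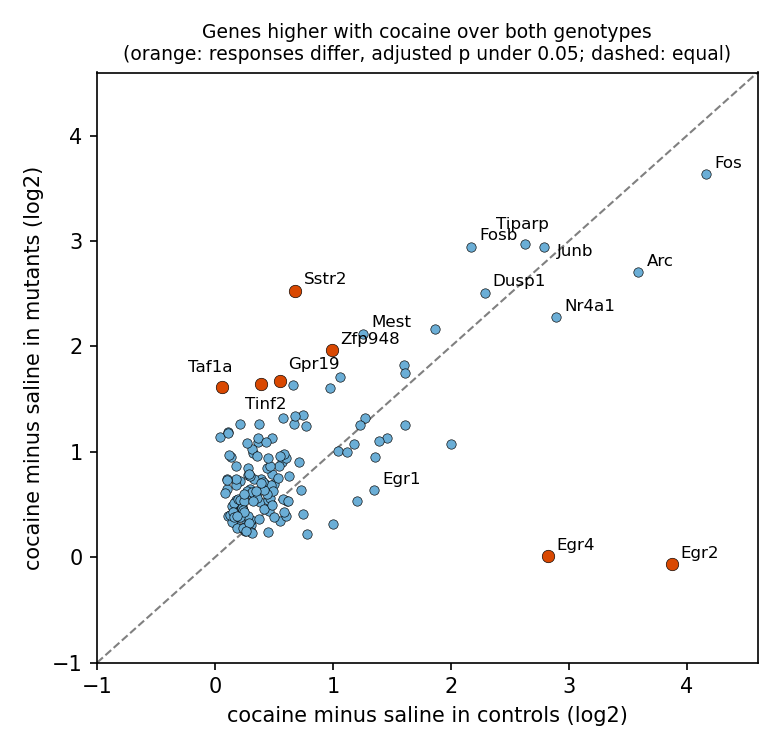
Response to cocaine in controls (x axis) and mutants (y axis), both log2, for the 154 genes called as higher over both genotypes; the dashed line marks equal responses and orange points the genes whose responses differed at an adjusted p under 0.05. Egr2 and Egr4 lie near 0 in mutants, Fos at 4.16 and 3.64, and 121 of the 154 genes lie on the side of the larger response in mutants.

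Averaged over both genotypes, cocaine raised Fos 14.9-fold, Arc 8.85-fold, Junb 7.29-fold and Tiparp 6.98-fold. Frmd6, a FERM domain protein gene, rose 3.27-fold and Mest 3.22-fold. The largest falls were small, with Ddit4l at −0.52 (SE 0.124, adjusted p = 0.0498), Kcnip1, a potassium channel interacting protein gene, at −0.47 (1 of its 2 probe sets called), Pard6g at −0.38 and the deubiquitinase gene Usp2 at −0.35. A total of 257 probe sets were called, 234 higher and 23 lower. By list, 11 of 14 immediate early transcription factors rose (13 adjusted over the list alone), 10 of 16 effectors (12 adjusted over the list alone), 9 of 10 SRF-bound genes (9 adjusted over the list alone), 5 of 9 CREB-bound genes (5 adjusted over the list alone) and 4 of 9 MAPK feedback regulators (5 adjusted over the list alone). These 5 calls held with an estimated correlation, with adjusted p of 0.00211, 0.00158, 0.00158, 0.00595 and 0.0405, as did glucocorticoid-responsive genes (2 of 13 rose, 7 adjusted over the list alone; adjusted p = 0.0163). Clock genes (3 of 14 rose, 3 adjusted over the list alone; adjusted p = 0.168 with an estimated correlation), heat shock genes (3 of 12 rose, 5 adjusted over the list alone; adjusted p = 0.175 with an estimated correlation) and glial activation (0 of 3 called, 1 fell adjusted over the list alone; adjusted p = 0.143 with an estimated correlation) lost theirs. SRF cytoskeletal genes had 0 of 28 members called by limma with cocaine, and 0 adjusted over the list alone.

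Between genotypes, several actin cytoskeleton genes were lower in mutants and several genes for striatal neuropeptides were higher. Over both treatments, Actg1, which encodes cytoplasmic gamma-actin, was 2.38-fold lower (log2 change −1.25, SE 0.0617, adjusted p = 7.65e-08). The filament crosslinker gene Flna was 2.30-fold lower (−1.20, SE 0.126) and the tropomyosin gene Tpm1 2.26-fold lower (−1.18, SE 0.0702). Pdyn, the precursor of dynorphin peptides made by D1 medium spiny neurons, was 4.59-fold higher (2.20, SE 0.0872, adjusted p = 8.74e-09), and Cartpt, the precursor of CART peptides, was 2.64-fold higher (1.40, SE 0.196, adjusted p = 0.000569).

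Other genes lower in mutants were Wnt2 (−1.63), Gdpd5 (−1.27), the synaptic vesicle protein gene Synpr (−1.25), the calcium sensor gene Doc2b (−1.22), the synaptic adhesion gene Lrrtm1 and the cadherin gene Cdh9 (both −1.22), and Inhba (−1.18). Higher were Fam43a (2.25), the endothelial lipase gene Lipg (2.19), the selenium-independent glutathione peroxidase gene Gpx6 (1.82), the immunoglobulin heavy chain gene Ighm (1.59, with its other probe set at 3.09), Tpbg (1.41), Chmp1b (1.37) and Rab3b (1.32). The control levels of Lipg (2.35 after saline) and Fam43a (3.46 after saline) and the mutant levels of Wnt2 (2.91 after saline) and Inhba (3.18 after saline) lay under the filter's floor of 4. In all, 1051 probe sets differed over both treatments, 490 higher and 561 lower in mutants, and 2602 passed an unadjusted p under 0.05.

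Of 28 tested SRF cytoskeletal target genes, 8 were lower and 3 higher in mutants over both treatments, with the same numbers adjusted over the list alone. The lower members were Actg1, Flna, Tpm1, Actb (−0.91), Vcl (−0.60), Cap1 (−0.53), Wdr1 (−0.51) and Cfl1 (−0.23), and the higher ones Itga5 (1.25), Tpm2 (0.52) and Pfn1 (0.28). Itga5 read 3.56 and 3.52 in controls after saline and cocaine, under the filter's floor of 4, where folds depend on the background correction. Probe sets disagreed for Actb, whose dimmer one read 0.34 without a call, and for Cfl1, whose other one read −0.13 without a call. The list as a whole was not called by camera, with a median change of −0.02 (adjusted p = 0.155 at the preset correlation). Camera looks for a shift of a list in 1 direction, so this result does not speak against the changes of single members. Tpm3, the brightest uncalled member of the list, read 0.04, and its other probe sets down to −0.06. Under saline 6 members were lower and 1 higher (8 and 3 adjusted over the list alone; adjusted p = 0.054), and under cocaine 6 and 1 (7 and 2 adjusted over the list alone; adjusted p = 0.123).

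**Figure D4:**
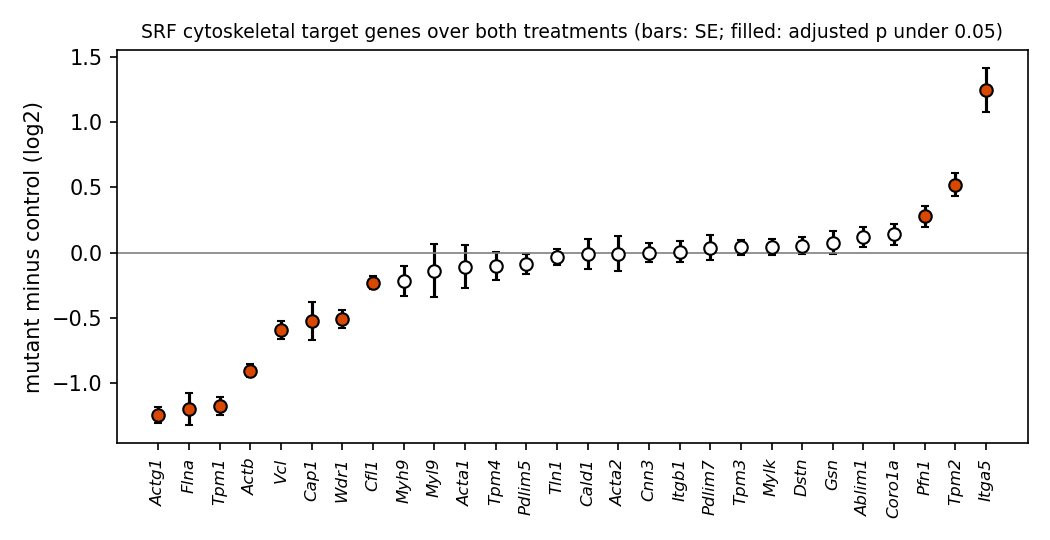
Mutant minus control change (log2, y axis) of the 28 tested SRF cytoskeletal target genes (x axis) over both treatments, with limma's SE as bars and filled points for an adjusted p under 0.05. The changes run from −1.25 for Actg1 to 1.25 for Itga5, with 8 called lower and 3 called higher.

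D1 medium spiny neuron genes were higher in 4 of 5 tested members (4 adjusted over the list alone), Pdyn, Sfxn1 (0.42), the tachykinin precursor Tac1 (0.35) and the transcription factor gene Isl1 (0.24, 1 of its 2 probe sets called). The list has 10 members, and Drd1 and Chrm4 were among those not tested. Its mean of 0.663, against a median of 0.351, was raised by Pdyn at 2.20. Of D2 medium spiny neuron genes, 1 of 3 was called, the enkephalin precursor Penk (0.19, 1 adjusted over the list alone), and Drd2 read 0.14. Dopamine, opioid and neuropeptide genes were higher in 5 of 9 (5 higher and 1 lower adjusted over the list alone), including the cannabinoid receptor gene Cnr1 (0.63). CREB-bound genes were higher in 6 of 9 and lower in 1 (8 and 1 adjusted over the list alone), with Dusp1 (0.95) and the coactivator gene Ppargc1a (0.67, 4 of its 5 probe sets called) higher and the G protein regulator gene Rgs2 (−0.59) lower. The D1, neuropeptide and CREB lists held with an estimated correlation (adjusted p = 0.0138, 0.0138 and 0.0262). All of them hold Pdyn, and the neuropeptide list also shares Tac1 with the D1 list and Penk and Sst with the CREB list. How far these calls depend on Pdyn was not tested. Effector genes were higher in 7 and lower in 2 of 16 (10 and 3 adjusted over the list alone), with Arc (0.83) and Plk2 (0.53) higher and Inhba lower, a call lost at adjusted p = 0.528 with an estimated correlation.

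Immediate early transcription factors went both ways over both treatments, with 5 of 14 higher and 3 lower (6 and 3 adjusted over the list alone) and no call of the list (adjusted p = 0.891); its median was −0.05, its mean 0.00419 and the test's direction up. Fos (1.27), Nr4a1 (1.01), Fosb (0.92), Junb (0.80) and Crem (0.58) were higher, and Egr2 (−2.13), Egr4 (−1.20) and Egr1 (−0.46) lower. The Egr differences lay mainly under cocaine. Under saline, mutants and controls read 3.83 and 4.0 for Egr2, 2.11 and 1.90 for Egr4, and 9.26 and 9.37 for Egr1. After cocaine they read 3.77 and 7.87, 2.12 and 4.73, and 9.90 and 10.72. The saline levels of Fosb, like those of Egr4, lay under the filter's floor of 4. The SRF-bound immediate early genes had 5 of 10 higher and 4 lower, the same adjusted over the list alone, and were not called by camera (adjusted p = 0.83). The 4 lower members were Egr2, Egr4, Egr1 and Srf itself, the mutated gene. The median of the list was 0.36, while its mean of −0.09 and the test, which both include Srf, pointed down. Of 15 astrocyte, 13 oligodendrocyte, 12 microglia and 10 endothelial or pericyte genes, 1, 0, 1 and 0 were called, namely Slc4a4 (0.49, 2 of its 3 probe sets called) and the lysosomal gene Cd68 (0.72), both higher. The microglial receptor gene Csf1r read −0.11 and the astrocyte gene Clu 0.05, with none of their other probe sets called and those of Clu differing in sign (−0.02 to 0.11).

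The remaining lists were not called by camera over both treatments. Genes shared by medium spiny neurons went both ways, with 4 of 16 higher and 4 lower (5 and 5 adjusted over the list alone; adjusted p = 0.509), among them the phosphodiesterase gene Pde1b (0.39) and the G protein regulator gene Rgs9 (−0.33). Of 9 ionotropic glutamate and GABA receptor genes, Gria2 (−0.45, 1 of its 2 probe sets called) and Gabrd (−0.31) were lower (3 adjusted over the list alone; adjusted p = 0.509). Clock genes had 2 of 14 higher and 3 lower (3 and 4 adjusted over the list alone; adjusted p = 0.924), with Per3 at −0.47. MAPK feedback regulators had 3 of 9 higher (3 adjusted over the list alone; adjusted p = 0.334) and glucocorticoid-responsive genes 2 of 13 (2 higher and 1 lower adjusted over the list alone; adjusted p = 0.174). Heat shock genes had 1 of 12 higher, Dnajb1 (0.43), and 1 lower, Hspa5 (−0.33), the same adjusted over the list alone (adjusted p = 0.891). Chromatin regulators had 1 of 8 higher, Hdac5 (0.36), and 1 lower, Ehmt2 (−0.21, 1 of its 2 probe sets called), with 2 and 1 adjusted over the list alone (adjusted p = 0.891). Of 3 cortical projection neuron genes, the transcription factor gene Mef2c (−0.69) was lower (2 adjusted over the list alone; adjusted p = 0.334). Striatal interneuron, thalamus, choroid plexus, blood, glial activation and apoptosis genes had 0 members called by limma, with adjusted p of the lists of 0.509, 0.924, 0.83, 0.632, 0.968 and 0.968. The median, mean and test differed in sign for heat shock, chromatin, glial activation and apoptosis genes.

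Under saline alone, 331 probe sets differed, 149 higher and 182 lower in mutants. Pdyn was 4.30-fold higher, Fam43a 3.69-fold, Gpx6 3.42-fold and the integrin gene Itga5 3.22-fold, and Nr4a1 (1.32) and Arc (1.27) were also higher. Srf was 3.93-fold lower, Wnt2 3.04-fold, the synaptotagmin gene Syt9 2.58-fold and Gdpd5 2.54-fold. The control levels of Fam43a and Itga5 and the mutant level of Wnt2 lay under the filter's floor of 4. The CREB-bound (2 of 9 higher), D1 (2 of 5) and neuropeptide lists (4 of 9) were called and held (adjusted p = 0.0376, 0.028 and 0.0176 with an estimated correlation), with 6, 2 and 6 higher and 1, 0 and 1 lower adjusted over the list alone. Immediate early transcription factors had 1 of 14 higher (4 adjusted over the list alone; adjusted p = 0.671 with an estimated correlation). Without replicate 3 of the saline-treated mutants 219 probe sets were called, without replicate 3 of the saline-treated controls 220, and with only the saline arrays in the fit 152.

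Under cocaine, 465 probe sets differed, 252 higher and 213 lower in mutants. Egr2 was 17.2-fold lower and Egr4 6.11-fold lower, and Srf (−1.68), Wnt2 (−1.65), Flna (−1.31) and Actg1 (−1.27) were also lower. Lipg was 6.62-fold higher, Fam43a 6.10-fold, Sstr2 5.08-fold and Pdyn 4.89-fold, and Fosb (1.31), Dusp1 (1.06), Crem (0.90) and Dnajb1 (0.88) were higher too. The CREB-bound (4 of 9 higher, 1 lower), D1 (2 of 5 higher) and neuropeptide lists (3 of 9 higher) were called and held (adjusted p = 0.0324, 0.0158 and 0.028 with an estimated correlation). Effector (5 of 16 higher, 2 lower) and glucocorticoid-responsive genes (2 of 13 higher) were called and lost the call (adjusted p = 0.307 and 0.344 with an estimated correlation). Adjusted over the list alone, 6, 5, 4, 9 and 3 members of these 5 lists were higher, and 1 CREB-bound gene and 2 effectors lower. Of the probe sets called under saline, 83 of the 149 higher and 117 of the 182 lower were called in the same direction under cocaine, where independent lists would share 3.38 and 3.49. Both comparisons use the same estimate of the spread, so their calls are not fully independent. Fewer probe sets were called without replicate 1 of the cocaine-treated mutants (265) or without replicate 1, 2 or 3 of the cocaine-treated controls (308, 306 and 267). Array weights gave 708, and groups taken from the description field 0.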

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

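The tests of a weaker activation of mutants as a whole, of probes that fail in mutants, of a lower starting level, of the genes near Srf and of the shares of glial, vascular and neuronal cells were chosen only after the result was seen, as was the count of neighbours in 1 direction; the others were set before.

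The difference between the genotypes' responses to cocaine passed its own test for 8 probe sets. Both Egr2 probe sets (differences of −3.94 and −4.31) and Egr4 (−2.82) responded less in mutants. Taf1a (1.56), Sstr2 (1.85), Tinf2 (1.25), Gpr19 (1.12) and Zfp948 (0.976) responded more. Of 100 splits drawn from the 200 that relabel genotype within treatment, 9 gave at least 8 probe sets, the real one included, and the highest other split gave 48. Chance can therefore not be excluded for the number of 8. The split with 48 exchanges 2 saline-treated controls for 2 saline-treated mutants, which brings differences in level between the genotypes into the term tested, a structure of the samples that their labels give.

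By list, a difference in response was called at the preset correlation for immediate early transcription factors (adjusted p = 6.34e-07), SRF-bound immediate early genes (4.9e-07), activity-regulated effectors (0.0235), microglia (0.0235), glial activation (0.033), glucocorticoid-responsive genes (0.00279) and heat shock genes (0.0199). None of these 7 held with an estimated correlation (adjusted p of 0.309 to 0.598).

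Egr2 and Egr4 rose with cocaine in controls and showed no called change in mutants. A weaker activation of the mutants as a whole would lower the response of the other rising genes, but their mean response was larger in mutants by 0.276 (log2, SE 0.0748, exact permutation p = 0.175). A smaller response of some strong responders stays open, with differences of −0.52 for Fos, −0.89 for Arc, −0.93 for Btg2, −0.71 for Egr1 and −0.61 for Nr4a1, none called. Btg2 and Egr1 ended lower in cocaine-treated mutants than controls (4.915 and 9.90 against 5.66 and 10.72). Fos, Arc and Nr4a1 ended higher (9.51, 8.415 and 9.78 against 8.50, 8.03 and 9.07), from higher saline levels (5.87, 5.71 and 7.50 against 4.34, 4.44 and 6.18). Fosb (0.77), Tiparp (0.35), Gadd45b (0.30), Dusp1 (0.23) and Junb (0.15) differed the other way, also without a call. No single array carries the difference of Egr2 and Egr4, since the highest adjusted p of their 3 probe sets over the 12 fits without 1 array was 0.000592. Probes that fail in the mutants cannot be told apart from a lost response for Egr4, which differed by 0.205 under saline (log2, SE 0.161), because its saline level of 1.90 in controls is below the floor, where a failing probe would show no drop. The genotype, the biological explanation that the design gives, stays open and was not tested apart from these.

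More probe sets were called with cocaine in mutants (213) than in controls (50), and most rising genes had the larger response in mutants. The ratio of the numbers was at least 2.43 over the 12 fits without 1 array (131 and 141 probe sets in mutants without replicate 1 or 2 of the cocaine-treated mutants), which argues against 1 deviating array. A lower starting level in saline-treated mutants is argued against by a mean level of the rising genes 0.139 higher there (log2, SE 0.049). The difference in mean response did not pass the exact permutation test (p = 0.215). In that test, relabelling within a treatment brings in the genotypes' differences in level (0.139 after saline and 0.368 after cocaine). The test therefore cannot decide between biology and chance for a larger response in mutants, and both stay open. A difference in handling, injection or dose between the groups was not tested.

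Many probe sets (1051) differed between genotypes over both treatments. A shift in the share of glial or vascular cells as large as the median called change is argued against by their lists. Their largest median change was 0.0897 (log2, SE 0.0266, oligodendrocyte list) against 0.368 for the median size of the called changes. The called changes are those that passed the threshold, so a smaller shift in these shares stays open. The SE of a list median was taken over the genes of the list as if independent, and does not hold the spread between arrays. Another share of neuron types stays open, since the D1 medium spiny neuron list had a median of 0.351 (log2, SE 0.485) over only 5 genes and the cortical projection neuron list −0.18. Of the 100 tested genes nearest to Srf 11% were called, against 10.7% of the other genes (Fisher's exact test, p = 0.871). These were 11 called genes near Srf and 699 elsewhere. No excess of calls near Srf was detected. A window of 100 genes could not hold most of the calls whatever its rate, so the test cannot decide on strain variants. Variants around the mutated gene stay open, whether they act on genes in this window, lie further away or act on distant genes. Strain segments anywhere in the genome stay open too, though neighbours that are regulated together could give the same excess: 94 pairs of adjacent tested genes were both called, against a median of 75 in 10000 shuffles (permutation p = 0.0144), and 57 pairs in the same direction against 38 (permutation p = 0.0019), and the genotype was not separated from these.

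Over both treatments, 1 of 100 drawn splits, the real one, gave 1051 probe sets for genotype and the highest other gave 48, which makes chance unlikely for a number of this size. The same held for cocaine, with 1 of 100 at 257 and the highest other at 45. The comparisons of 3 against 3 arrays have 10 splits, too few for a share under 0.05, and in each 1 split reached the real number. The real numbers and highest others were 50 and 0 for cocaine in controls, 213 and 0 in mutants, 331 and 1 for genotype under saline, and 465 and 0 under cocaine.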

How the results depend on the processing

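All settings but 1 were set before the data were examined; leaving Egr2 and Egr4 out of the responding genes was chosen after. No called result turned its direction; the falling genes' difference in response, which was not called, did. Of 222 called gene results, 67 lost the call under at least 1 of 23 settings and 0 reversed. Further median or quantile scaling moved no number of called probe sets by over 1.5 times.

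Without the filter on dim probe sets, the difference in response was called for 5 probe sets in place of 8, and the falling genes' response differed by −0.12 (exact permutation p = 0.015). That difference was −0.036 with the stricter filter (exact permutation p = 0.36) and −0.059 as a median over genes (exact permutation p = 0.72). Array weights gave 88 probe sets for cocaine in controls and 708 for genotype under cocaine. With only the saline arrays in the fit, genotype under saline gave 152, with fewer arrays behind the spread. At adjusted p under 0.1, genotype gave 529 under saline, 777 under cocaine and 1656 over both. Groups from the description field gave 83 for cocaine in controls and 0 for genotype under cocaine. With estimated correlations, 5 lists were called for cocaine in mutants, 0 for the difference and 3 for genotype under cocaine. Apart from the fit of fewer arrays and the looser threshold, the cause was not tested.

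Leaving out each array in turn gave 131 to 240 probe sets for cocaine in mutants (131 and 141 without replicate 1 or 2 of cocaine-treated mutants), 219 to 350 for genotype under saline (219 and 220 without replicate 3 of saline-treated mutants or controls) and 265 to 537 under cocaine (265 without replicate 1 of cocaine-treated mutants, and 308, 306 and 267 without replicate 1, 2 or 3 of cocaine-treated controls). Called lists numbered 3 to 8 for the difference (3 without replicate 3 of cocaine-treated controls, 4 without replicate 2 of saline-treated controls or mutants), 4 to 9 for genotype under saline (9 without replicate 1 of saline-treated controls, 8 without replicate 2 of saline-treated mutants) and 4 to 7 over both (7 without replicate 3 of saline-treated mutants). The falling genes' difference ran from −0.27 to 0.010, the latter without replicate 1 of saline-treated controls, and passed the threshold without replicate 3 of saline-treated mutants (exact permutation p = 0.02).

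The replicate numbers did not pair the arrays: residuals of same-numbered arrays correlated at −0.145 to 0.116, and 2 of 12 arrays were closest to their own number. With the number as a block, 46 probe sets were called for cocaine in controls, 178 in mutants, 7 for the difference and 907 for genotype over both treatments. Dim genes such as Egr4 have signals at the floor in most groups, so their folds depend on the background correction, which was not varied.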

Other observations

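The sterol list was written after 8 of its tested members had been seen, the tests on the other members were set before their values were seen, and the tests of all members together and of the GABA genes were chosen only after the result was seen.

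Genes of sterol synthesis were higher in mutants. Of 16 tested members, 9 were called as higher over both treatments and 0 as lower, 12 higher adjusted over the list alone, and all 16 had a change above 0, from 0.09 to 0.73. The reductase gene Dhcr7, which makes cholesterol in the last step of its pathway, was 1.66-fold higher (log2 change 0.73, SE 0.0872, adjusted p = 0.000164). The methylsterol oxidase gene Msmo1 was 1.61-fold higher, the sterol carrier gene Stard4 1.49-fold, Idi1 1.40-fold and the epoxidase gene Sqle 1.38-fold. Srebf2, which encodes the transcription factor that controls the pathway, was 1.29-fold higher. The 8 members that had not been seen before the list was written, with a median change of 0.244 and 8 of 8 above 0, also lay above the other genes (camera p = 0.000113 at the preset correlation and 0.0102 with an estimated one). Their median was 0.277 under saline (8 of 8 above 0) and 0.177 under cocaine (7 of 8 above 0). They were measured on the same arrays as the members seen before, so they are not independent support. A rise of the pathway as a whole may therefore be followed up as a hypothesis; 2 of these 8 passed the test over all genes, Sc5d (0.35) and Fdft1 (0.33, 1 of its 2 probe sets), and 5 adjusted over the list alone. With cocaine, 0 of the 16 members were called by limma in controls and 2 in mutants, where Idi1 (0.56) and Pmvk (0.69) rose.

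The genes for the GABA-synthesising enzymes were higher in mutants over both treatments, both chosen after their values were seen. Both probe sets of Gad1 were called, at 0.57 and 0.35, and Gad2 read 0.60 (adjusted p = 0.00762).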
